A study of Rattus norvegicus with 12 samples.

How the data were processed

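The study comprised 12 single-colour arrays, 6 from rats on a high-protein diet and 6 from rats on a normal-protein diet. Per the labels' protocols, total RNA from colonic epithelium of male Wistar rats was labelled with Cy3. The animals weighed 180 to 200 g at the start and ate the diet for 6 weeks. The array was Agilent's whole rat genome design with 4 arrays on a slide. Per the file headers, each array was scanned at 532 nm with a photomultiplier gain of 600. The spots were measured with GenePix Pro 6.1.0.4, and the deposited intensities were not normalized. Each array held 45220 spots, of which 2343 were controls, and the 42877 gene spots carried 30367 distinct probes. The series value table, per the labels, was given as log2 values, and the submitters' processing notes name RMA with no version or role. Its background correction, filter and centring are not given in the sources used here. As held here, the table had column medians of 4.40, 4.45, 4.43, 4.40, 4.43 and 4.36 for normal protein replicates 1 to 6, and of 4.41, 4.40, 4.39, 4.41, 4.40 and 4.41 for high protein replicates 1 to 6. With its IDs moved by 1 row, its slopes against log2 signal minus background lay between 0.968 and 1.04 over bright probes only. With the IDs as given its rows did not match the scanner values, as described below. Scale and direction are thus known with the IDs so moved, and the centring is not.

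The deposited files per array hold intensity on a linear scale: the mean and median pixel of each spot, the median of its local background, and the signal minus the array's negative controls. Deposited flags mark spots as good (value 100) or not found (value -50). The share of gene spots flagged good ran from 42.67% to 55.86% across arrays. The 75th percentile of signal minus background ran from 130 to 385 intensity units. The number of arrays limits the precision of every comparison.

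The design fixed before the data were examined assumed a processed signal scaled to each array's 75th percentile. The files hold GenePix intensities without such a signal, so the background was corrected with normexp (offset 50) on the mean pixel and the median local background. The arrays were then quantile normalized on the log2 scale, which had been listed among the alternatives beforehand. Control spots were left out after the background step, and spots of one probe were averaged. A probe was tested where at least 0.5 of its spots were flagged good on at least 6 of the 12 arrays, whatever their diet. Of several probes of a gene, the one with the highest mean over all arrays was used. This left 10451 genes, 8857 of them with a gene symbol, from 13204 tested probes, of which 1467 had no name. Among 1180 genes with more than 1 tested probe, the probes of 337 differed in the sign of the diet difference. Names came from RefSeq accessions in a gene table of the GRCr8 assembly, which matched 18355 of the 26038 probes with an accession. Other probes kept the array's own gene name, and no coordinates were used.

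Diets were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene was called higher or lower only past that threshold. In addition, 43 gene lists covering protein-related metabolism, epithelial cell types, defence, stress, other cell types and colon position were fixed before the data were examined. A list's score on an array is the mean log2 value of its tested genes. Scores were compared with an exact two-sided permutation test over all 924 assignments of the 12 arrays into 6 and 6, with Benjamini-Hochberg adjustment over the 41 lists that had at least 5 tested genes. Camera with a preset correlation of 0.01, camera with an estimated correlation, and fry were run beside it. Whole profiles were compared by the mean Pearson correlation between arrays of the same diet minus that between arrays of different diets, with an exact one-sided permutation test.

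The genes named were chosen by a rule fixed beforehand. With fewer than 20 genes past the threshold, the 10 genes with a symbol and the smallest p on each side were named. For each list that did not pass, up to 2 members with the smallest p were named. Genes known only by a locus number or an accession were counted and not named. Names outside this rule are said to have been chosen after their values were seen.

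The gene fit was tested on simulated data for this comparison. Known changes of 1.5, 2, 3 and 4-fold were mixed in each draw, spread evenly over 200 of the 10451 genes. They were added to the real residuals under shuffled labels, over 20 draws. Each simulated group held 3 arrays of each real diet. The fit called 61.3% of genes changed 1.5-fold, 89.7% of those changed 2-fold, 96.3% of those changed 3-fold and 98.7% of those changed 4-fold. The larger changes ease the adjusted threshold for the smaller ones. These shares therefore do not give the power of a comparison with few changed genes. Of all simulated calls, 10.3% were genes that had not been changed, above the 5% that the threshold aims at. With 8 lists shifted at once, the list test called 21.9% of those shifted by 0.25 and 55% of those shifted by 0.5 on the log2 scale. A single shifted list could not be called, since the smallest exact p (0.00217) adjusts to 0.089 over 41 lists. Slides were taken from the file headers: 3 slides held 4 arrays each, 2 per diet, so slide was used as a block and differences were also computed within slides. Alternatives covered the background correction, the scaling, the filter, the handling of several probes, the replicate number and the slide as blocks, array weights, the variance prior, each array left out in turn and the deposited value table. Further alternatives were chosen after seeing the data: the median pixel, a colon-position score as a covariate, signal minus background with 75th percentile scaling, and the value table with its IDs as given. Moving the IDs of the value table by 1 row was likewise decided after seeing the data.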

Results

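Gene expression in samples labelled as rat colonic epithelium was measured after 6 weeks on a high-protein or a normal-protein diet. The question was how the colon's transcripts respond to more dietary protein. Each diet had 6 replicate arrays, and no pair of arrays held identical values. Nothing in the labels says which replicates came from separate animals, so the tests measure the spread between these samples. Signal differed between arrays: normal protein replicate 3 was the dimmest, with 42.67% of its gene spots flagged good, and high protein replicate 3 had the highest share at 55.86%. All expression values below are normalized log2 intensities, and differences are high protein minus normal protein.

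Among single genes, the smallest p-values on the high side belonged to Flcn, Fkbp5, Rnf186 and Aldh1a1. Those on the low side belonged to Tmx4, Sdf2l1, Csf1r and H2bc12. Aldh1a1, which makes retinoic acid from retinaldehyde, had the largest difference among these 8 genes. It was measured at 11.49 ± 1.16 (SD, n = 6) on high protein and 9.31 ± 0.71 (SD, n = 6) on normal protein, a ratio of 4.55. None of the 10451 tested genes passed the threshold in limma, where the smallest adjusted p was 0.68. At an unadjusted p under 0.05 there were 694 genes, 383 with higher and 311 with lower values on high protein, where chance alone would give 522.6. With normexp and 75th percentile scaling the split was 318 higher and 481 lower. A plain gene-by-gene test with Benjamini-Hochberg adjustment also called 0 genes.

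The 10 genes of smallest p on the high side lay above the normal-protein mean in 6 of 6 high-protein arrays. They were picked for a small p on these same arrays, so this count adds no evidence. Flcn (folliculin), which acts in the mTORC1 nutrient pathway, differed by 0.48 ± 0.10 (SE). Fkbp5, a glucocorticoid-induced co-chaperone, was at 8.11 ± 0.24 (SD, n = 6) against 7.50 ± 0.22 (SD, n = 6). Rnf186, a ubiquitin ligase, was at 11.29 ± 0.29 (SD, n = 6) against 10.64 ± 0.24 (SD, n = 6). Pbld1 differed by 0.75 ± 0.17 (SE), and Ppargc1b, a coactivator of mitochondrial genes, by 0.34 ± 0.08 (SE). The differences of Pam, the enzyme that amidates peptide hormones, and of Chka, a choline kinase, were 0.56 and 0.33. Those of Ppan, a ribosome assembly factor, and of Aasdh were 0.31 and 0.46. Adjusted over all genes with limma, each of these genes had a p of 0.68.

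On the low side, several of the 10 genes act in protein folding and stress in the endoplasmic reticulum. Sdf2l1 was at 9.36 ± 0.23 (SD, n = 6) on high protein and 9.88 ± 0.20 (SD, n = 6) on normal protein. Hsp90b1, the chaperone GRP94, differed by -0.36 ± 0.09 (SE), Manf by -0.40 ± 0.10 (SE) and Fkbp11, a prolyl isomerase, by -0.57 ± 0.14 (SE). Interferon-inducible Oas1k and Ifi27l2b differed by -0.95 ± 0.23 (SE) and -0.82 ± 0.20 (SE). Csf1r, the receptor that maintains macrophages, was at 6.66 ± 0.18 (SD, n = 6) against 7.04 ± 0.11 (SD, n = 6). Tmx4, H2bc12 and C1qtnf6 had differences of -0.40, -0.39 and -0.66. All 10 lay below the normal-protein mean in 6 of 6 high-protein arrays, each with an adjusted limma p of 0.68. That count, too, largely follows from picking genes for a small p on these same arrays. With slide as a block 0 genes passed, with a smallest adjusted p of 0.50. Within single slides limma called 0, 0 and 1 genes, the last being Bik on slide 3, where both high-protein arrays stood near 13 and every other array of the series was between 7.02 and 7.51.

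**Figure D1:**
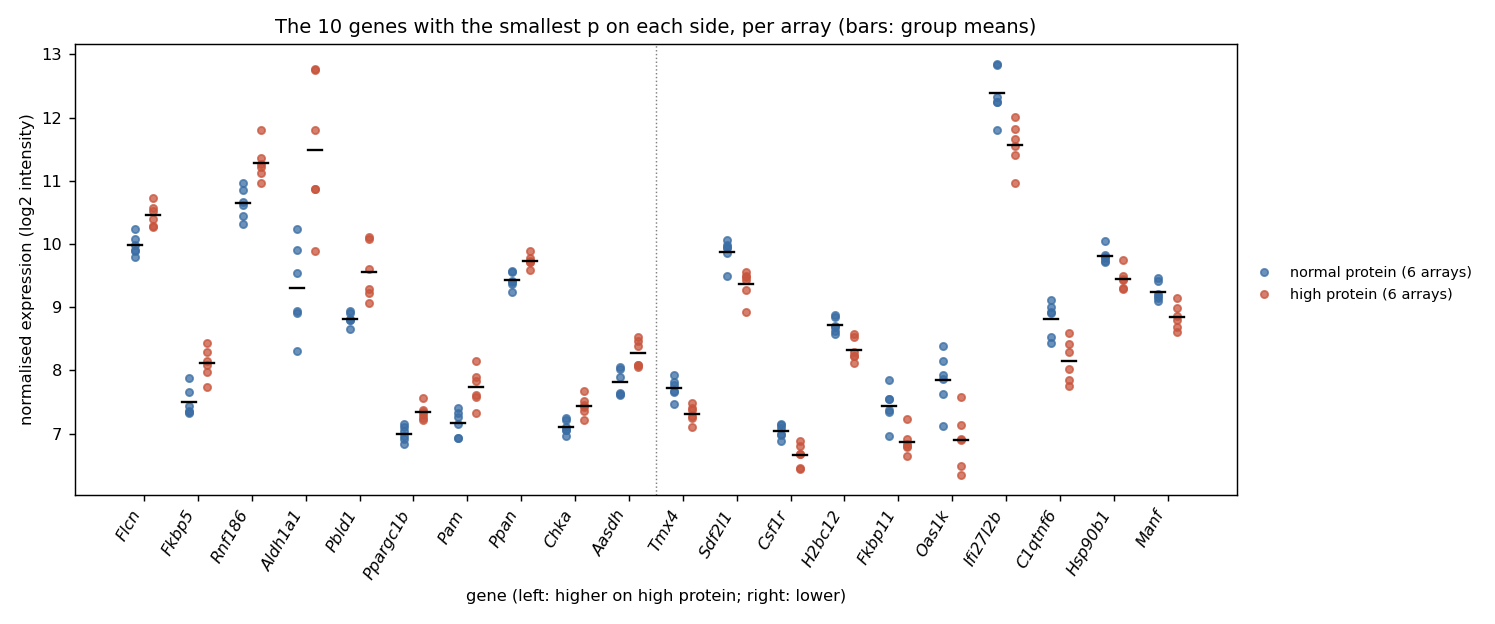
Normalised expression (log2 intensity, vertical axis) of the 10 genes with the smallest p on each side (horizontal axis), 1 point per array, blue for normal protein and red for high protein, with bars at the means of 6 arrays. Aldh1a1 shows the widest spread, from 9.89 to 12.77 on high protein and from 8.31 to 10.23 on normal protein.

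Genes 2-fold or more apart between diet means numbered 55, of which 32 had higher and 23 lower values on high protein. Of these, 19 had an unadjusted p under 0.05. Besides Aldh1a1 they included the metallothioneins Mt1 and Mt2A, the quinone reductase Nqo1, and Zg16, a goblet cell lectin. Mt1 and Mt2A were chosen after their values were seen, as were Bik, Hspa5, Hoxb13 and Hoxa13 in this account. Mt1 was at 14.19 ± 0.30 (SD, n = 6) on high protein and 12.76 ± 1.38 (SD, n = 6) on normal protein. For 95.46% of the genes the 95% interval of the difference lay within 2-fold either way, and for 84.68% within 1.5-fold. The offset of 50 in the background correction shrinks the fold of dim genes, and median signal minus background was 23 to 66 across arrays. These shares and the 2-fold counts hold for values with the offset and do not bound the fold of the signal itself.

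Most list differences below depended on single arrays. With each array left out in turn, 36 of the 41 list differences moved more than 1.5 times or changed sign, and 16 changed sign. The 5 that stayed within 1.5 times were the enteroendocrine, integrated stress, oxidative stress, macrophage and dendritic, and small-intestinal lists.

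Lists on amino acid and nitrogen handling, the metabolism most directly tied to protein intake, showed small differences. The amino acid transport list differed by 0.03 (exact p = 0.47). Within it, the glutamine carrier Slc38a1 was at 7.13 ± 0.12 (SD, n = 6) against 6.87 ± 0.17 (SD, n = 6), and Slc1a1 differed by 0.33 ± 0.15 (SE). Branched-chain amino acid breakdown differed by -0.01 (exact p = 0.69), with Auh at -0.22 and Dld at -0.15. Genes of ammonia, arginine and polyamine metabolism differed by -0.02 (exact p = 0.65), with Azin1 at -0.23 and Sms, spermine synthase, at 0.24. Sulfide oxidation differed by -0.11 (exact p = 0.45), and 9 of its 10 genes lay below 0, among them Tst at -0.30 and Suox at -0.19. The sulfide list ran from -0.22 to -0.05 with single arrays left out, and within the slides it differed by -0.36, 0.06 and -0.04. None of the 4 lists passed. The sign of the amino acid transport list turned, to -0.01, with normexp and 75th percentile scaling.

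Genes that burn fat and make ATP followed the same picture. Fatty acid oxidation and ketogenesis differed by -0.08 (exact p = 0.41), with Hadhb at -0.30 ± 0.10 (SE) and Eci1 at -0.30 ± 0.15 (SE), and by -0.03 without normal protein replicate 6. Of 56 oxidative phosphorylation genes, 36 lay below 0, among them Cycs, cytochrome c, at -0.25 and Atp5po at -0.20. Their list differed by -0.03 (exact p = 0.28) and turned to 0.02 with median scaling. Transport and sensing of short-chain fatty acids differed by -0.04 (exact p = 0.77), with Bsg at -0.29 and the butyrate carrier Slc5a8 at 0.47. Slc5a8, like Slc1a1 and Fabp2 in this account, also varied with Hoxb13 minus the mean of Hoxb6 and Hoxb7, a score of colon-position genes. Cholesterol synthesis differed by 0.06 (exact p = 0.71), its median member lay below 0 at -0.03, and Ebp was at 0.25. The bile acid response list differed by -0.05 (exact p = 0.83) although its median member was at 0.03. In it Nr1i2, the pregnane X receptor, was at 9.86 ± 0.26 (SD, n = 6) against 9.48 ± 0.18 (SD, n = 6), and Abcc3 differed by 0.19.

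Lists of epithelial cell types were scored in samples that also carried signal of other cells. The smooth muscle score, for one, was 10.46 on high protein and 10.64 on normal protein, so values are not of epithelium alone. Goblet and mucus genes differed by -0.24 (exact p = 0.29), with 21 of 27 genes below 0. That list ran from -0.38 without normal protein replicate 6 to -0.12 without high protein replicate 3, and differed by -0.14, 0.01 and -0.57 within the slides. Zg16 was at 12.44 ± 0.56 (SD, n = 6) against 13.56 ± 0.72 (SD, n = 6). The trefoil peptide Tff1 was flagged good in 5 normal-protein arrays and in 1 high-protein array, so no difference is given for it. Enteroendocrine genes differed by -0.37 (exact p = 0.13), with 10 of 12 genes below 0. Among them were Tph1, which starts serotonin synthesis, at -0.91 ± 0.33 (SE) and Chgb at -0.87 ± 0.47 (SE). Of the 12 genes, 2 fell with the score of colon-position genes (Hoxb13 minus the mean of Hoxb6 and Hoxb7), Chgb among them. With that score in the fit the enteroendocrine list differed by -0.35. Tph1 was at 6.80 to 7.64 in the arrays with Hoxb13 near or above 12 and at 7.77 to 8.98 in the others. Most arrays of the former kind were high-protein arrays, so diet and this pattern overlap in the Tph1 difference. Among arrays of the former kind, Tph1 was at 7.64 and 7.61 on normal protein and at 6.80 to 6.97 on high protein. In the others the diets overlapped, with 7.91 to 8.98 on normal protein and 7.77 and 8.49 on high protein. A Tph1 difference thus remained among the former arrays, which are few, and no test was made within them. All 6 tuft cell genes lay below 0 (list -0.15, exact p = 0.19), with Alox5ap at -0.22 and Avil at -0.20. The cell cycle list differed by -0.09 (exact p = 0.52) with Nusap1 at -0.33 and Ccna2 at -0.27. It ran from -0.17 to -0.03 with single arrays left out and was at 0.18 on slide 2. The stem cell and Wnt list differed by 0.02 (exact p = 0.83) with Prom1 at -0.40 and Slc12a2 at 0.29. Tight junction and adhesion genes had a mean difference near 0 (exact p = 0.996), with Ocln, occludin, at 0.48 ± 0.18 (SE) and Dsp, desmoplakin, at 0.27 ± 0.10 (SE).

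Colonocyte ion transport differed by 0.09 (exact p = 0.58) and by -0.03 without normal protein replicate 6. It held the bicarbonate carrier Slc4a7 at 0.59 ± 0.25 (SE) and Atp12a, the colonic proton pump, at 2.56 ± 1.31 (SE). Atp12a varied between 5.83 and 11.17 within normal protein and between 6.27 and 12.78 within high protein. It followed Hoxb13, a gene of the distal colon. Hoxb13 was near or above 12 in 2 normal-protein and 4 high-protein arrays and lower in the other arrays. Hoxb6 and Hoxb7, whose expression marks more proximal gut, were above 10 in normal protein replicate 6 and in high protein replicates 3 and 4. Their diet differences were 0.85 ± 0.90 (SE) and 0.72 ± 0.89 (SE). The posterior Hox list differed by 0.20 (exact p = 0.31), with Hoxd10 at 0.90 ± 0.35 (SE) and Cdx2 at -0.44 ± 0.20 (SE). Its largest difference was that of Hoxb13, at 1.55. With members scaled to unit SD the posterior Hox difference was -0.10, and without normal protein replicate 6 it was 0.11. The anterior Hox list had 3 genes, too few to test, and differed by 0.56. Small-intestinal markers differed by -0.18 (exact p = 0.18), with the fatty acid binding protein Fabp2 at -1.56 ± 0.63 (SE) and Anpep at 0.17.

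**Figure D2:**
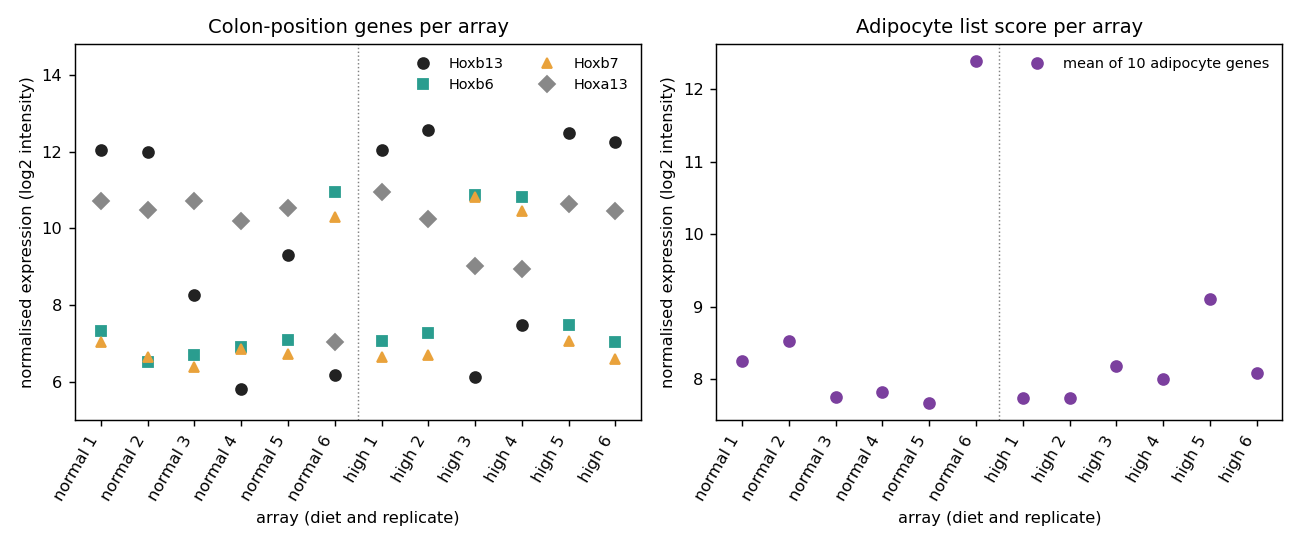
Left, normalised expression (log2 intensity) of Hoxb13, Hoxb6, Hoxb7 and Hoxa13 in each of the 12 arrays; right, the mean of the 10 adipocyte list genes in each array, with a dotted line between the diets. Hoxb6 and Hoxb7 stand above 10 in normal protein replicate 6 and high protein replicates 3 and 4, and the adipocyte score of normal protein replicate 6 is 12.39, where no other array exceeds 9.11.

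The unfolded protein and integrated stress list differed by -0.18 (exact p = 0.087, adjusted exact p = 0.87), and 26 of its 32 genes were below 0. Its members included Sdf2l1, Hsp90b1 and Manf as above, and Hspa5, the chaperone BiP, at -0.53 ± 0.18 (SE). At an unadjusted limma p under 0.05, 6 members were lower and 1 higher on high protein, the latter being Cebpb at 0.24. The largest difference in the list, Atf3 at -0.92, rested on normal protein replicate 3. Atf3 was at 13.31 there and between 6.62 and 9.48 in the other arrays. Cebpb and Atf3 were chosen after their values were seen. Adjusted over the list alone, Sdf2l1, Hsp90b1 and Manf passed with limma (adjusted p = 0.017 for Sdf2l1), while 0 passed over all genes. Over all 43 lists, 7 members passed in this way. That adjustment takes no account of the number of lists searched, so some passes can arise by chance. The list's difference was -0.22, -0.16 and -0.15 within the 3 slides. The oxidative stress list, which holds Nfe2l2 among other genes, had the smallest list p. Its difference of 0.11 was larger than in every other assignment of the arrays but its mirror (exact p = 0.0022, the smallest this test can give). Over the 41 lists its adjusted p was 0.089, the lowest that a single list can reach with 12 arrays, so this test could neither call it nor rule it out. It differed by 0.03, 0.13 and 0.18 within the slides. Its members were divided, 20 above and 20 below 0, and the median member was at 0.01. The largest differences in it were those of Mt2A, Mt1 and Nqo1, at 2.24, 1.43 and 1.33. Nqo1 was at 9.22 ± 0.89 (SD, n = 6) against 7.89 ± 0.64 (SD, n = 6), while Nfe2l2 itself differed by -0.50 ± 0.14 (SE). With members scaled to unit SD the exact p was 0.17.

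Other stress lists lay close to 0. The p53 and DNA damage list differed by 0.02 (exact p = 0.43), with Zmat3 at 0.20 and Phlda3 at -0.41. It turned to -0.01 with both kinds of 75th percentile scaling. Xenobiotic metabolism differed by -0.06 (exact p = 0.65), and of its members Aldh1a1 passed adjusted over the list alone (limma adjusted p = 0.019). Abcc3, at 0.19, also belongs to it. Immediate early genes differed by -0.02 (exact p = 0.88), with Hspb1, a small heat shock protein, at -0.57 and Ier2 at 0.21. The circadian clock list differed by 0.04 (exact p = 0.62) and was just below 0 with the deposited signal minus background scaled to the 75th percentile. Fkbp5 passed in it adjusted over the list alone (limma adjusted p = 0.0048), and Cry2 was at -0.14.

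Among defence genes, the interferon response list differed by -0.16 (exact p = 0.34), with 20 of 28 genes below 0, and by -0.06 without normal protein replicate 6. Oas1a, an antiviral enzyme, was at 6.71 ± 0.48 (SD, n = 6) against 7.60 ± 0.37 (SD, n = 6) and passed adjusted over the list alone (limma adjusted p = 0.047). Isg20 was at -0.27. On slide 1 the list lay higher on high protein, by 0.28, and on slides 2 and 3 it differed by -0.41 and -0.35. Chemokines differed by -0.09 (exact p = 0.27), with Ccl5 at -0.57 ± 0.22 (SE) and Cxcl16 at 0.37 ± 0.15 (SE). The TNF and NF-kB list differed by 0.03 (exact p = 0.44), turned to -0.005 with normexp and 75th percentile scaling, and held Ikbkb at 0.20 and Traf1 at 0.20. Apoptosis genes differed by -0.004 (exact p = 0.93), with Cycs as above and Prf1 at -0.26. That mean near 0 includes Bik at 1.95, from the 2 high-protein arrays of slide 3, while all 4 members with an unadjusted p under 0.05 were lower on high protein. Antimicrobial defence differed by 0.14 (exact p = 0.28), with Il17ra at 0.23 and the calcium-binding protein S100g at 1.62 ± 0.72 (SE). The median member of the antimicrobial list was at 0.01, with 11 genes above and 10 below 0, and S100g had its largest difference. MHC class I genes differed by 0.01 (exact p = 0.92), with B2m at -0.27 and RT1-M3-1 at -0.19. MHC class II genes differed by 0.03 (exact p = 0.89), with Ctss at 0.21 and Ciita at 0.20.

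Markers of cells other than epithelium lay lower on high protein in 9 of 10 tested lists, none of which passed, and 2 of the 9 changed sign without normal protein replicate 6. All 16 macrophage and dendritic cell genes were below 0 (list -0.25, exact p = 0.078), and the list differed by -0.34, -0.19 and -0.21 within the 3 slides. Csf1r passed adjusted over this list alone (limma adjusted p = 0.015), and Itgam was at -0.36 ± 0.12 (SE). Smooth muscle genes differed by -0.18 (exact p = 0.35), with Pln at -0.74 and Tagln at -0.32, and 20 of 21 were below 0. Much of this came from high protein replicate 4, without which the smooth muscle list differed by -0.04. Fibroblast genes differed by -0.14 (exact p = 0.26), with Col5a2 at -0.39 and Lum at -0.47, and by -0.06 without normal protein replicate 6; on slide 3 the fibroblast list was at 0.08. Enteric neuron and glia genes differed by -0.17 (exact p = 0.26), with Snap25 at -0.19 and Vip at -0.36. They ran from -0.26 to -0.09 with single arrays left out and were at 0.13 on slide 3. Mast cell genes differed by -0.20 (exact p = 0.29), with Cpa3 at -0.31 and Mcpt8 at -0.41. B and plasma cell genes differed by -0.19 (exact p = 0.37), with Mzb1 at -0.61 and Fcrla at 0.41. T and NK cell genes differed by -0.05 (exact p = 0.64), with Gzmm at -0.27 and Prf1 at -0.26, and their median member was at 0.03. Endothelial genes differed by -0.07 (exact p = 0.81), with Cldn5 at -0.25 and Ramp2 at -0.16, and turned to 0.07 without normal protein replicate 6. The adipocyte list differed by -0.59 (exact p = 0.65), with Dgat2 at -1.10 and Lpl at -0.76. Without normal protein replicate 6, whose adipocyte genes stood far above all other arrays, its sign turned, to 0.14. Erythrocyte genes differed by 0.24 (exact p = 0.50), with Bpgm at -0.22 and Hbb at 0.41. The erythrocyte list differed by 0.02 without normal protein replicate 3 and by 0.52 without normal protein replicate 6. The neutrophil and eosinophil list had 3 genes, too few to test, and differed by 0.20, with S100a9 at 0.51 and Ncf1 at 0.16. Snap25, Lpl, S100a9 and, among small-intestinal markers, Anpep were flagged good in only 2 of 6 arrays of one diet, so their differences are uncertain in size.

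**Figure D3:**
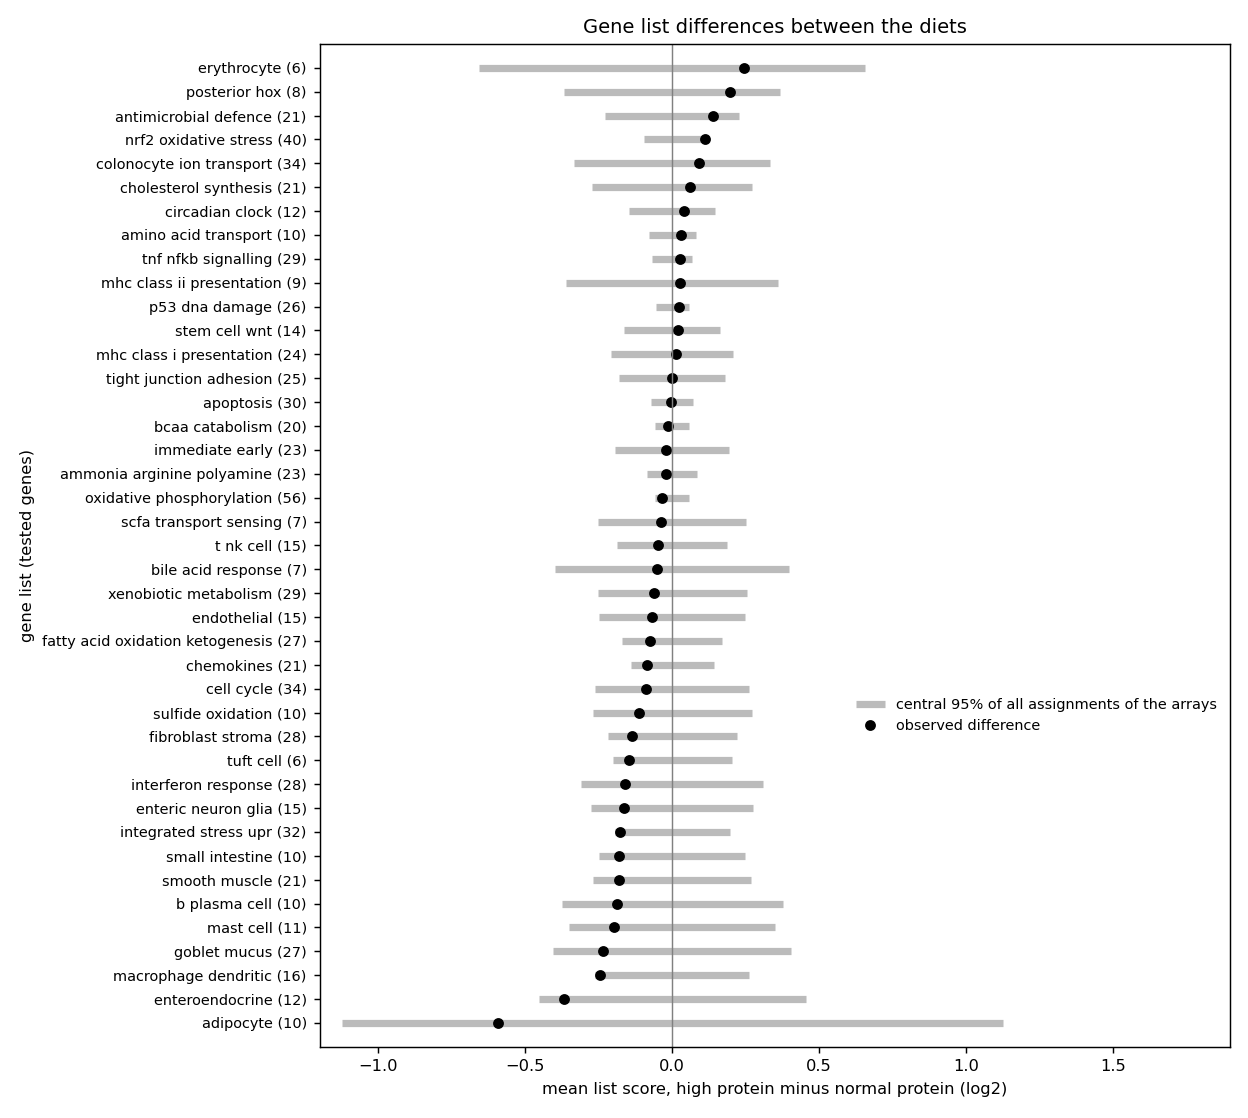
Difference in mean list score between the diets (log2, horizontal axis) for the 41 tested gene lists (vertical axis, number of tested genes in brackets); black points are observed differences and grey bars the central 95% of differences over all 924 assignments of the 12 arrays. The oxidative stress list, at 0.11, is the one point outside its grey bar.

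Across the lists, the exact permutation test called 0 of 41 after adjustment, with 1 list at an unadjusted p under 0.05, and 28 lists lay lower and 13 higher on high protein. No list could pass alone, only together with others of similarly small p. Without normal protein replicate 6, 7 lists changed sign: adipocyte (0.14), endothelial (0.07), branched-chain breakdown (0.004), xenobiotic metabolism (0.007), colonocyte ion transport (-0.03), stem cell and Wnt (-0.04) and MHC class II (-0.07). Without that array other lists moved further from 0, such as enteroendocrine (-0.50), mast cell (-0.32), tuft cell (-0.22) and erythrocyte (0.52). Others moved nearer to 0, such as interferon response (-0.06) and fibroblast (-0.06). Fry called 0 lists (smallest adjusted p = 0.80). Camera with a preset correlation called 8 lists, all lower on high protein: macrophage and dendritic, integrated stress, enteroendocrine, smooth muscle, interferon response, fibroblast, cell cycle, and enteric neuron and glia. With an estimated correlation it called 0, and each of these 8 lists had an adjusted p = 0.84 with an estimated correlation.

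Over the profile of all tested genes, arrays of one diet were hardly closer to each other than to arrays of the other diet. The mean Pearson correlation between arrays was 0.96393 within a diet and 0.96284 between diets. The difference of 0.00109 was no larger than other splits gave (exact one-sided permutation p = 0.23). The closest pair crossed the diets, normal protein replicate 1 with high protein replicate 1 (0.985), and the most distant pair was normal protein replicate 6 with high protein replicate 2 (0.923).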

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

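The tests on colon position, on fat markers and on the row displacement of the value table were chosen after the results were seen; the count of other splits, and the match of each column of the value table to its own array, were chosen before. Of 298 groups of 6 values (list scores, named genes and array measures), 32 held an array set apart from the other 5 by more than Dixon's critical share of the range. Chance gives about 1 in 20 such groups.

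Fat genes stood out in normal protein replicate 6. Its adipocyte score was 12.39, where the other normal-protein arrays lay between 7.67 and 8.53. Adipoq (adiponectin) was at 13.28, Cfd at 14.78, Fabp4 at 13.14 and Retn at 13.42 in that array; these 4, and Hoxa7, Hoxa13 and Hoxb13 below, were chosen after their values were seen. Dgat2 stood at 12.21 and Lpl at 10.90. All 10 tested adipocyte genes were highest there, as were all 11 probes of these genes with the median pixel in place of the mean, which argues against faults of single spots. Diet as the source finds no counterpart in the other arrays: without that array the list differed by 0.14 (exact p = 0.69). Fat tissue in that sample is a candidate source, and how it came there was not tested. High protein replicate 5 had the next highest adipocyte score, 9.11 against 7.74 to 8.18 in the other high-protein arrays.

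Arrays of both diets differed in genes of colon position. In normal protein replicate 6, Hoxb6 was at 10.95 and Hoxb7 at 10.29, and the anterior Hox score was 10.48, where the other normal-protein arrays had scores between 7.75 and 8.10. High protein replicates 3 and 4 were like it. The slide does not account for this, since Hoxb13 minus the mean of Hoxb6 and Hoxb7 ranged over 10.13 within a single slide and over 10.29 in all. Diet does not either, as arrays of both diets lay on both sides of 0 (exact p = 0.72). Tissue taken at different positions along the colon may be the source: Hoxa13, not used in that score, was lower in these 3 arrays than in each of the other 9, by at least 1.15, and Hoxa7 was above all other arrays in 2 of the 3.

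The deposited value table did not match the scanner files row by row. With the IDs as given, the rank correlation between a column and its own array had a median of 0.12, and with the IDs moved by 1 row it was at least 0.967 in all 12 columns. A displacement of the table's IDs by 1 row, as the table is held here, is consistent with this. Exchanged columns are argued against, since 12 of 12 columns matched their own array best. Column medians lay between 4.36 and 4.45. With the IDs moved by 1 row, slopes on the log2 signal of bright probes were near 1, and the centring stays unknown.

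Other values of normal protein replicate 6 stood apart too. Its tight junction score was low at 8.80 (others 9.09 to 9.26) and its endothelial score high at 8.70 (others 7.72 to 8.01). Hadhb was at 8.29, Phlda3 at 7.96, Sdf2l1 at 9.49 and Slc1a1 at 6.31. Its mean correlation with the other 11 arrays was 0.938, where the other normal-protein arrays had 0.966 to 0.971.

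In the other normal-protein arrays, replicate 1 stood apart with a macrophage score of 9.04, Hsp90b1 at 10.04 and Slc4a7 at 8.13. In replicate 2 the antimicrobial defence score was 10.49 and Fcrla was at 7.93. Replicate 3, the dimmest array, had a TNF and NF-kB score of 8.05 and Il17ra at 10.40.

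Among high-protein arrays, replicate 1 had a B and plasma cell score of 8.02 (others at most 7.37) and Mzb1 at 7.81. Replicate 2 had a low amino acid transport score, 7.60, Cldn5 at 6.47 and a neutrophil and eosinophil score of 8.02. Replicate 3 had an immediate early score of 8.41 (others 8.85 to 8.98), an endothelial score of 8.18 and Dsp at 8.79. Replicate 4 had a smooth muscle score of 9.78, where the other high-protein arrays lay between 10.41 and 10.74. Replicate 6 had a T and NK cell score of 7.30, and the 75th percentile of its signal minus background was 385, the brightest of the group.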

How the results depend on the processing

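The median pixel, the position score, signal minus background scaled to the 75th percentile and the value table with its IDs as given were chosen after seeing the data. So was the move of that table's IDs by 1 row. With all slides together, limma called 0 genes between the diets under every alternative run but the value table with its displaced IDs, which gave 1; within slide 3 alone it called Bik. A plain gene-by-gene test with no adjustment and at least 2-fold counted 11 genes. The exact test called 0 lists throughout, but over 41 lists it cannot call 1 list alone in any setting (lowest p 0.00217, or 0.031 and 0.0093 with the replicate number and the slide as a block), so this is no sign of stability. Camera called 8 lists with a preset correlation and 0 with an estimated one.

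Genes at an unadjusted p under 0.05 numbered 694. They were 1259 with no filter (21914 genes tested), 1321 with array weights, 1056 with the position score as a covariate and without normal protein array 6, and 1099 with the position score and the slide as a block; the cause was not tested. Leaving out each array in turn gave 488 to 878 such genes, 0 called genes and 0 called lists in every case. The similarity difference then ran from 4.69e-05 (without normal protein replicate 4) to 0.00275 (without high protein replicate 3). With the displaced IDs it was -0.00054. For the oxidative stress list, the adjusted exact p ran from 0.089 to 0.88 over the alternatives other than the displaced table.

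The replicate number as a block gave 0 called genes and 813 at an unadjusted p under 0.05. Deviations of same-numbered arrays correlated between -0.11 and 0.40 across genes, and 3 of 6 matched their own number best. This does not settle whether the numbers mark pairs, and the labels do not say. The main fit took no pairs. With the replicate block the smallest adjusted limma p was 0.34, against 0.68 without it. Of 98 named genes, 0 changed sign under the alternatives that held them, apart from the displaced table, where 49 did; the filter on all 12 arrays kept 63 of them. Genes chosen for a small p tend to keep their sign on the same arrays, so this says little about stability. Apart from that table, up to 7 of the 41 list scores changed sign under one alternative, each without passing. A random slide block was not run, since every slide holds both diets. Signal over background limits the dim probes: 10451 of 21914 genes passed the filter.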

Other observations

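The tests here were chosen after the values were seen, apart from the counts over other splits of the arrays. Several genes with a wide spread between arrays of one diet were high where Hoxb13 was high. Fxyd4, a regulator of ion pumps, ranged from 5.95 to 13.73 over the 12 arrays, Sftpd, a secreted defence lectin, from 7.47 to 13.94 and B3gnt7, a glycosyltransferase, from 7.24 to 13.65. The lectin-like Mptx1 (6.16 to 14.42) and Retnlb, a goblet cell peptide (6.09 to 13.60), did not follow Hoxb13 through all arrays. They were low only in the 3 arrays with high Hoxb6 and Hoxb7, and high in normal protein replicate 4, where Hoxb13 was at 5.83. On the opposite side, Car1, a carbonic anhydrase, Fabp1, Cyp4f1 and Bpifb9a were highest where Hoxb13 was low. Bpifb9a was at 13.79, 12.73 and 14.32 in the 3 arrays with high Hoxb6 and Hoxb7, and between 6.54 and 11.89 in the others. These genes, and the others named in this part, were chosen after their values were seen.

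In a limma fit that held diet, 618 genes besides the 3 score genes varied with Hoxb13 minus the mean of Hoxb6 and Hoxb7, 355 rising and 263 falling with it. With the score shuffled over the arrays 99 times, at most 1 gene was called. The arrays fall into clusters on this score, so the count describes these arrays and no correlation is given. Against 618 of all 10451 tested genes, 8 of 34 ion transport genes rose and 1 fell with the score. Of 21 antimicrobial genes 4 rose and 1 fell, and of 23 immediate early genes 4 rose. On the other side, 3 of 10 sulfide oxidation genes and 4 of 23 ammonia and arginine genes fell, with 0 and 1 rising, and xenobiotic genes were divided (3 up, 4 down of 29). No test of these shares was made. Variation with this score, whatever its source, could hide a diet response or produce a diet difference. Hoxb13 was near or above 12 in 4 high-protein and 2 normal-protein arrays. Atp12a, Slc5a8, Slc1a1, Chgb and Fabp2, whose diet differences are given above, were among the genes that varied with the score. With the score in the fit, limma called 0 genes for diet (adjusted p = 0.33 at the smallest).

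Besides fat genes, normal protein replicate 6 had Reg4 at 13.25 and Spink4 at 13.26, against means of 6.74 and 7.22 in the other 11 arrays. Both are secretory cell genes of the gut. In 39 genes a single array stood more than 4 above every other array, such as Ppp1r37 in high protein replicate 1 (by 6.44), Kcnj5 in high protein replicate 4 (by 6.34) and Ovol2 in high protein replicate 2 (by 5.93). These occurred in 11 of the 12 arrays.

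Chance was not excluded for the counts between the diets at an unadjusted p or by camera. For called genes the comparison is empty: the real count is 0, so all 100 of 100 splits of the 12 arrays into 6 and 6, the real one included, reach it. Among the other splits 4 called any gene, the highest 24, and the cause was not tested. At an unadjusted p under 0.05, 22 of 100 splits gave at least the real 694 genes, and the highest other gave 1275. For lists called by camera with a preset correlation, 73 of 100 splits gave at least the real 8, and the highest other gave 19.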
